A study of Mus musculus with 19 samples.

How the data were processed

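Total RNA from the hippocampus of 19 mice aged 4 months was measured by bulk RNA sequencing, with 1 library per animal. Per the labels' protocols, the animals were perfused with saline, the left hippocampus was frozen and pulverised, RNA was purified on columns with DNase treatment, and samples with an RNA integrity number of at least 7 went on to library preparation. Paired-end reads came from NovaSeq and HiSeq instruments, and the labels do not say which library ran on which instrument, nor whether the libraries keep the strand. Whether reads from overlapping genes on opposite strands were told apart is therefore unknown. The groups were 5xFAD females (n = 5), 5xFAD males (n = 5), 5xFAD females homozygous for the clusterin knock-in (n = 4) and males of that genotype (n = 5), taken from the genotype and sex in the labels. No batch, litter or date was given, and the animal numbers and library numbers of the 2 genotypes fall in separate ranges.

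The authors deposited 3 tables that cover all libraries. The first holds estimated counts per gene, which the authors deposited as whole numbers. Per the submitters' processing notes, FastQC, Salmon, DESeq2, Seurat and the mouse build mm39 were used, without versions or the step each served. The second deposited table holds normalized counts, a signal that the authors scaled by factors that differ from gene to gene and library to library. Within a library the log2 ratio of normalized to raw count varied with an SD of 0.117 to 0.252 over 10765 genes above 100 counts in every library. The third deposited table holds variance-stabilized values on the log2 scale. Of 486 genes with a count of 0 in at least 6 libraries, 481 had zeros in both sexes, and 481 of these 481 took a different value in females and in males at those zeros (tolerance 1e-06). The lowest total of any gene in the count table was 28 counts. Counts were used for all tests, the normalized values served as an alternative scaling, and the variance-stabilized values entered no test.

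The count table lists 20655 gene IDs, all naming a gene. GENCODE M21 on GRCm38 gave a symbol, biotype, length and GC content for 20023 of them (96.9%), and 632 stayed without a symbol. Because the authors' build was another one, no coordinates are given, only chromosomes and the order of neighbouring genes.

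Total counts ran from 17.28 to 25.2 M per library, where M stands for mega (19.7 ± 1.74 M, SD, n = 19). All 36 pairs of libraries within a group differed by more than sampling noise, with a chi-square per gene of at least 11.3, where 1 is noise. Xist and Ddx3y levels matched the labelled sex in 19 of 19 libraries.

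Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr on the 4 groups with its default minimum of 10 counts, robust dispersions, quasi-likelihood F-test), which left 18204 genes. Adjusted p values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. The genotype effect was fitted over all libraries with sex as a covariate. The genotype effect in females, the genotype effect in males, the genotype by sex interaction, the sex effect in 5xFAD and the sex effect in knock-in animals came from 1 model with a mean for each of the 4 groups. The interaction is the change with the knock-in in females minus that in males, and sex effects are female minus male. Levels are in CPM (counts scaled to library size) with TMM factors.

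Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 40 lists per comparison. The lists covered microglial states, interferon, antigen presentation, complement and cytokine genes, astrocyte states, synapses and neurons, other cell types of brain, vessels, meninges, ventricles and blood, neighbouring brain regions, amyloid and lipid handling, mitochondria, ribosomes and stress responses. Camera with an estimated correlation and fry were alternatives. An exact two-sided permutation of genotype within sex, on the mean of a list per animal, was added after seeing the data. Clu was compared on log2 CPM with an exact two-sided permutation test.

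The genes named in the text follow a rule. For the genotype effect these are Clu, App and Thy1, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 log2 CPM, and up to 3 members with the lowest p of each list described in detail. For the other comparisons these are the 5 largest rises and the 5 largest falls. A further gene fixed in the rule is not reported here. Where fewer passed, the 5 genes with the lowest p are given as values. Gene models without a symbol, predicted genes and pseudogenes were counted but not ranked by name. Genes outside the rule are said to have been chosen after their values were seen.

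Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2's size factors, library size only, no low-count filter, a stricter filter (1 CPM in at least 4 libraries), 1 surrogate variable (sva 3.50.0), no sex term, the replicate number as a block, fits within 1 sex or genotype, and each library left out. The alternatives chosen after seeing the data were the authors' own factors as offsets, offsets for GC content and gene length, thinning to the lowest depth, 5xFAD males 6 and 10 left out together, and a covariate for long noncoding RNA. That covariate is the mean log2 CPM of Malat1, Neat1, Meg3, Miat, Rian, Mirg, Snhg11 and Kcnq1ot1, transcripts known to be kept largely in the nucleus or to be long and noncoding.

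The tests were checked on counts simulated from the real means and depths with 50 genes changed by each fold. For the genotype effect, 20% of genes changed 1.25-fold, 62% of those changed 1.5-fold and 86% of those changed 2-fold were recovered among 17902 genes, with 5 false calls. For the genotype effect in females the shares were 6%, 48% and 78% of 17912 genes, and in males 12%, 38% and 88% of 17906 genes. For the interaction they were 4%, 4% and 44% of 17935 genes. For the sex effect they were 2%, 32% and 76% of 17898 genes in 5xFAD and 2%, 26% and 74% of 17923 genes in knock-in animals. Of 5 lists raised 1.25-fold for the genotype effect, 5 were recovered, and 0 of 28 untouched lists were called among 17925 genes. The simulated genes varied independently, which real genes do not, so the 0 of 28 does not carry over to the real libraries. There, other splits of the animals called a median of 11 lists for the genotype effect at the preset correlation. Limits given for genes without counts cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.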

Results

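Bulk RNA was sequenced from the left hippocampus of 19 mice aged 4 months. All carried the 5xFAD transgenes, which include mutant human amyloid precursor protein expressed in neurons and give plaques at an early age. Of these, 10 carried 5xFAD alone (5 females and 5 males), and 9 were also homozygous for a knock-in at the clusterin gene (4 females and 5 males). Clusterin, also called apolipoprotein J, is a secreted chaperone and lipid carrier made mainly by astrocytes in brain, and its human gene is a risk locus for Alzheimer's disease. The labels name the knock-in CLUh2kbKI without giving the sequence it changes. Depth was 21.33 ± 2.59 M counts in knock-in females (SD, n = 4; M stands for mega), 20.09 ± 1.54 M in knock-in males (SD, n = 5), 18.69 ± 0.593 M in 5xFAD females (SD, n = 5) and 19.02 ± 1.05 M in 5xFAD males (SD, n = 5). Libraries of animals without the transgenes are not analysed here.

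The largest axis of variation, which held 19.8% of the variance, followed long noncoding RNA. The mean log2 CPM of Malat1, Neat1, Meg3, Miat, Rian, Mirg, Snhg11 and Kcnq1ot1 correlated with it over 19 libraries (Pearson r = 0.944, Spearman rho = 0.837, permutation p = 1e-05 for each, the smallest the permutations can give). Without the 2 libraries farthest from the median, r was 0.907, and after removing group means it was 0.916. The same level served as the covariate chosen after seeing the data, and the permutation p values take no account of such a choice. This noncoding level was 6.56 ± 0.41 in knock-in females (SD, n = 4) against 8.21 ± 0.17 in 5xFAD females (SD, n = 5). It was 7.80 ± 0.53 in knock-in males (SD, n = 5) and 7.67 ± 0.72 in 5xFAD males (SD, n = 5), where male 10 stood at 6.45.

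**Figure D1:**
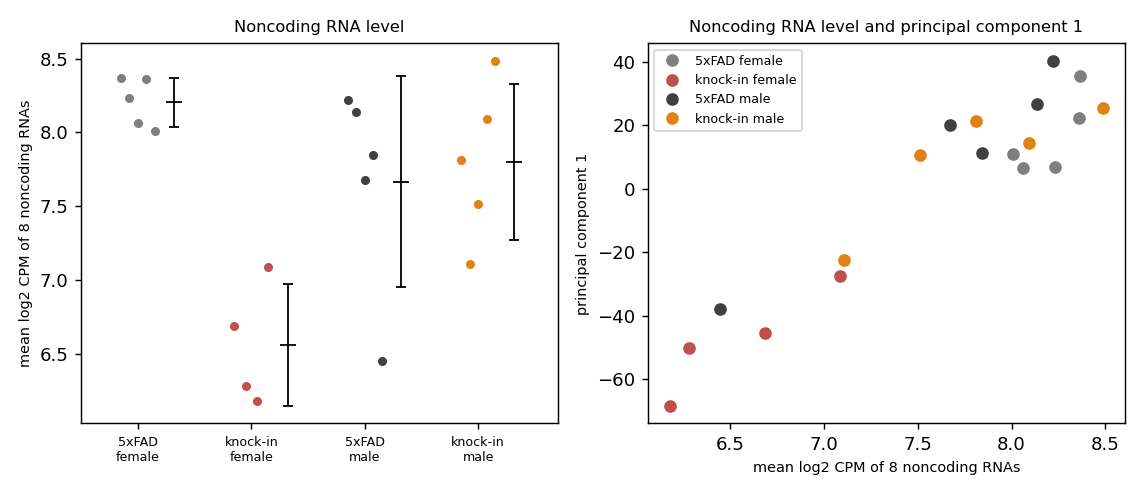
Mean log2 CPM of 8 long noncoding RNAs in each of 19 libraries by genotype and sex (points are animals, bars the mean and SD), and the same level against principal component 1. Knock-in females lie between 6.18 and 7.08, and 5xFAD females between 8.01 and 8.37.

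The knock-in gene itself was read first. Clu, on chromosome 14, was among the most abundant transcripts, at rank 80 of the tested genes. It stood at 1070 ± 214 CPM in knock-in animals (SD, n = 9) and 979 ± 120 CPM in 5xFAD animals (SD, n = 10), a log2 change of 0.13 (SE 0.10, edgeR adjusted p = 0.665). The difference was smaller than the spread between animals, with an exact permutation p of 0.292 within sex. By sex the log2 change was 0.29 in females (edgeR adjusted p = 0.233) and -0.02 in males (adjusted p = 0.987). The interaction did not pass (adjusted p = 0.427). Counts against a mouse reference need not include human sequence, so this level neither shows nor excludes extra clusterin. The transgene-related genes App (log2 change 0.11, adjusted p = 0.623) and Thy1, whose promoter drives the transgenes (0.28, adjusted p = 0.292), did not differ between genotypes past the threshold. For Thy1, 5 of 9 knock-in animals lay above all 5xFAD animals, and for App 0 of 9. Counts of mouse App and Thy1 need not include reads of the human transgenes. These levels therefore neither show nor exclude a difference in transgene expression.

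The comparison of genotypes over both sexes asks which RNAs differ with the clusterin knock-in in a hippocampus with amyloid pathology. Such differences may also come from colony, cohort or library batch, with which genotype is confounded. Knock-in animals had more RNA of 4 genes, of which 3 act in lysosomes or microglia and the other degrades amyloid-beta. Ide, which encodes the insulin-degrading enzyme, a protease that also cleaves amyloid-beta, rose from 54.3 ± 11.6 CPM (SD, n = 10) to 98.8 ± 15.1 CPM (SD, n = 9), a log2 change of 0.86 (SE 0.12, adjusted p = 0.0037), and 9 of 9 knock-in animals lay above the highest 5xFAD animal. Gusb, the lysosomal beta-glucuronidase, rose from 25.2 ± 3.1 to 34.7 ± 3.28 CPM (log2 change 0.47, SE 0.08, adjusted p = 0.0277). Olfml3, a secreted protein enriched in microglia, rose from 34.8 ± 5.59 to 52.8 ± 10.9 CPM (0.62, SE 0.10, adjusted p = 0.0277). Cd68, a lysosomal glycoprotein of phagocytes, rose from 19.7 ± 3.14 to 32.3 ± 8.13 CPM (0.73, SE 0.13, adjusted p = 0.0382). Ide, Gusb, Olfml3 and Cd68 lie on chromosomes 19, 5, 3 and 11, none of them that of Clu.

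The genes next in line did not pass. Gfap, the intermediate filament of reactive astrocytes, was at 1250 ± 202 CPM in knock-in and 864 ± 144 CPM in 5xFAD animals (log2 change 0.53, adjusted p = 0.0684). The junctional adhesion molecule F11r (0.58, adjusted p = 0.0684), the Fc receptor Fcgr3 (0.51, adjusted p = 0.0684), the lysosomal protease Ctsd (0.52, adjusted p = 0.0805) and the integrin Itgb5 (0.46, adjusted p = 0.0805) had values of the same sign. No gene fell past the threshold with edgeR or limma-voom, while 2166 genes had an unadjusted p under 0.05 and DESeq2 called 94 higher and 14 lower. Of 33 alternatives, the call of Ide was lost in 1, that of Gusb in 13, that of Olfml3 in 16 and that of Cd68 in 20. Leaving out 1 library gave 127 genes without 5xFAD male 10 (58 higher, 69 lower), 31 without knock-in female 1, 19 without knock-in male 10, 9 without 5xFAD female 2, 2 without 5xFAD female 4, and 1 without knock-in female 4 or 5, knock-in male 7, 8 or 9, 5xFAD female 1, or 5xFAD male 6 or 8.

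**Figure D2:**
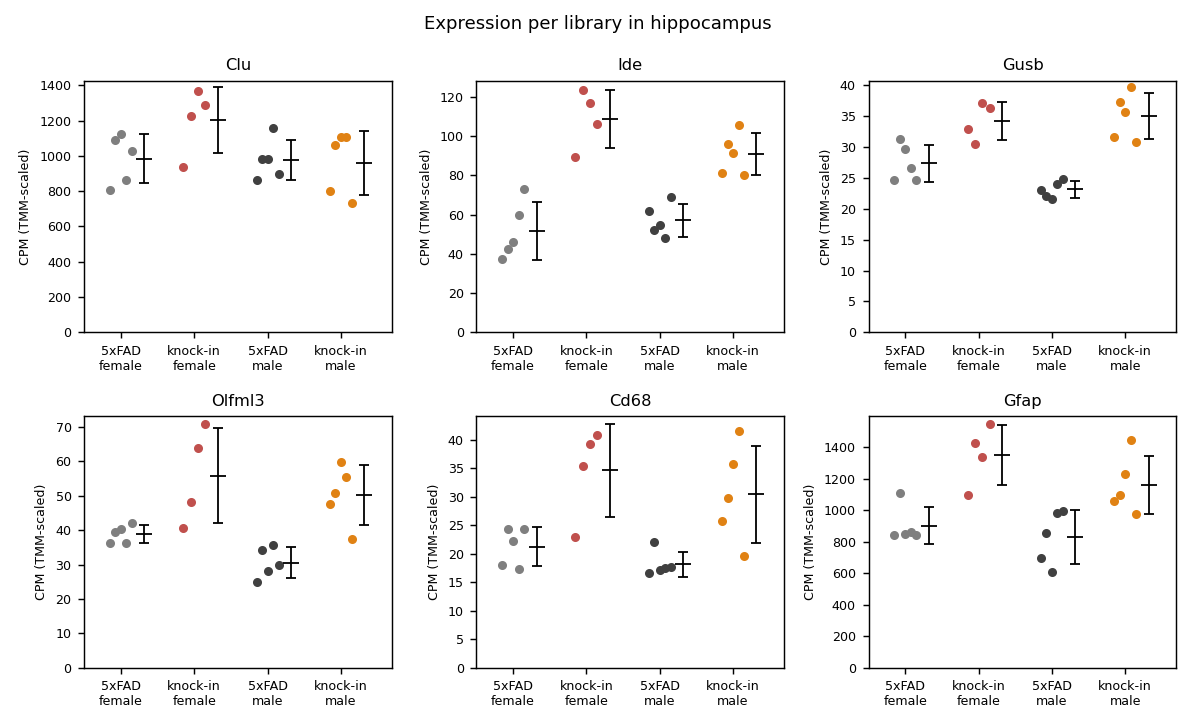
CPM of Clu, Ide, Gusb, Olfml3, Cd68 and Gfap in each animal by genotype and sex, with the mean and SD of each group. For Ide, 9 of 9 knock-in animals lie above the highest 5xFAD animal, whereas Clu overlaps between genotypes.

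Microglial genes rose as groups. Plaque-induced genes, a set known to rise around amyloid plaques, had a median log2 change of 0.41 over 53 members. Of these, 48 rose with p values adjusted over the list alone and 2, Gusb and Olfml3, over all genes (camera adjusted p = 6.83e-41, and 0.0265 with an estimated correlation). Disease-associated microglia genes had a median of 0.45 over 34 members, of which 23 rose adjusted over the list alone and 2, Cd68 and Gusb, over all genes (camera adjusted p = 6.76e-23, and 0.0262 with an estimated correlation). Homeostatic microglia genes went the same way, with a median of 0.38 over 18 members, 16 of them higher adjusted over the list alone and 1, Olfml3, over all genes (camera adjusted p = 1.61e-18, and 0.0265 with an estimated correlation). Among them were Spi1, the myeloid transcription factor (0.62, adjusted p = 0.148), and the Fc receptor-like Fcrls (0.44, adjusted p = 0.148), neither past the threshold over all genes. The plaque-induced list shares 14 genes with the disease-associated list and 6 with the homeostatic list, which share 1 with each other. Among the 34 plaque-induced genes in neither, 33 had a change above 0 (median 0.38).

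**Figure D3:**
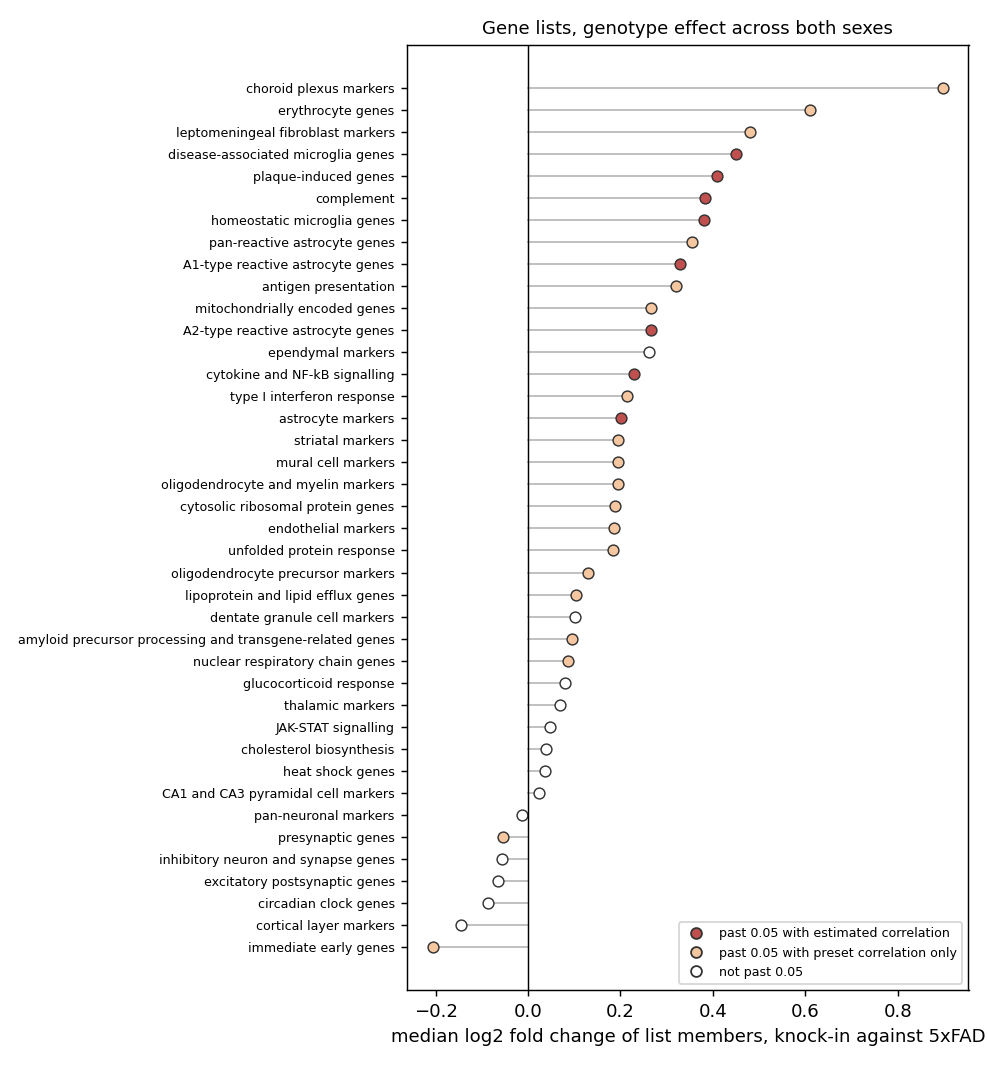
Median log2 change of 40 gene lists with the knock-in, over both sexes. Dark points passed an adjusted p of 0.05 with camera at a preset and at an estimated correlation (8 lists), pale points at the preset correlation only, and open points did not pass.

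Innate immune genes were higher too, in lists that share members with the microglial ones. Examples are Itgam and Itgax of the complement list and Ccl4 of the cytokine list. Complement genes had a median log2 change of 0.38 over 22 members, 8 of them higher adjusted over the list alone and 0 over all genes (adjusted p = 0.0411 with an estimated correlation). They include the integrins of complement receptors Itgam (0.37, adjusted p = 0.173), Itgax (0.63, adjusted p = 0.175) and Itgb2 (0.48, adjusted p = 0.155). Cytokine and NF-kB genes had a median of 0.23 over 16 members with 0 past the threshold adjusted over the list alone (adjusted p = 0.0278 with an estimated correlation). Named by their p were the chemokines Ccl4 (0.69, adjusted p = 0.326) and Cxcl10 (0.92, adjusted p = 0.357) and the receptor Tlr2 (0.41, adjusted p = 0.369). Antigen presentation genes (median 0.32, 22 members) and type I interferon genes (0.21, 33 members) passed at the preset correlation, with 0 members adjusted over the list alone. Their adjusted p was 0.228 and 0.497 with an estimated correlation. JAK-STAT genes did not pass (median 0.05, camera adjusted p = 0.745).

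Lists named for astrocytes were higher as well, but bulk RNA does not show which cells their members came from. Gfap and Serpina3n of the pan-reactive list are also plaque-induced genes. Astrocyte markers had a median log2 change of 0.20 over 16 members, all above 0, and 8 rose adjusted over the list alone (adjusted p = 0.0262 with an estimated correlation). They include Aldh1l1, a folate enzyme used as a marker (0.31, adjusted p = 0.213), Mlc1 (0.21, adjusted p = 0.272) and the glutamate transporter Slc1a3 (0.21, adjusted p = 0.284). The A1-type list had a median of 0.33 over 11 members and the A2-type list 0.27 over 11 members, each with 2 higher adjusted over the list alone (adjusted p = 0.0427 and 0.0262 with an estimated correlation). In the first, the complement inhibitor Serping1 (0.66, adjusted p = 0.228), the immunoproteasome subunit Psmb8 (0.46, adjusted p = 0.333) and the proteoglycan Srgn (0.42, adjusted p = 0.256) had the lowest p. In the second these were the glycosyltransferase B3gnt5 (0.95, adjusted p = 0.243), the lipopolysaccharide co-receptor Cd14 (0.49, adjusted p = 0.252) and the transglutaminase Tgm1 (0.83, adjusted p = 0.395). The pan-reactive list had a median of 0.36 over 12 members, with 2 higher adjusted over the list alone (adjusted p = 0.0991 with an estimated correlation). Besides Gfap it holds Serpina3n, a protease inhibitor of reactive astrocytes (0.37, adjusted p = 0.272), and the small heat shock protein Hspb1 (0.40, adjusted p = 0.333).

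Synaptic lists changed by small amounts, and their calls depended on the model. Presynaptic genes had a median log2 change of -0.05 over 25 members, with 0 past the threshold adjusted over the list alone (camera adjusted p = 0.0386, and adjusted p = 0.55 with an estimated correlation). Values were -0.26 for the active zone scaffold Pclo (adjusted p = 0.412), -0.15 for the calcium sensor Syt1 (adjusted p = 0.456) and -0.18 for the vesicle priming factor Unc13a (adjusted p = 0.611). Excitatory postsynaptic genes did not pass (median -0.07 over 22 members, camera adjusted p = 0.197). The AMPA receptor subunits Gria2 (-0.19, adjusted p = 0.408) and Gria3 (-0.16, adjusted p = 0.378) and the scaffold Homer1 (-0.26, adjusted p = 0.49) had the lowest p there. Inhibitory synapse genes (-0.06, camera adjusted p = 0.299) and pan-neuronal markers (median -0.01, mean 0.01, camera adjusted p = 0.745) did not pass. With the noncoding level as a covariate, at the preset correlation, presynaptic (-0.12, camera adjusted p = 2.46e-05), excitatory (-0.04, camera adjusted p = 0.0368) and inhibitory synapse genes (-0.08, camera adjusted p = 0.00514) were each called lower. Immediate early genes, which report recent neuronal activity, had a median of -0.21 over 18 members with 0 adjusted over the list alone (camera adjusted p = 0.00157, and adjusted p = 0.42 with an estimated correlation). They include Fosb (-0.49, adjusted p = 0.4), Npas4 (-0.53, adjusted p = 0.387) and Nr4a3 (-0.26, adjusted p = 0.365).

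Markers of vessels, blood, meninges and ventricles were higher in knock-in animals on balance and ranged widely between animals of a group. The noncoding level was 7.25 ± 0.80 in knock-in animals (SD, n = 9) and 7.94 ± 0.57 in 5xFAD animals (SD, n = 10). Median log2 changes were 0.90 for choroid plexus, 0.61 for erythrocytes, 0.48 for leptomeningeal fibroblasts, 0.20 for mural cells, 0.19 for striatum and 0.19 for endothelium. All 6 lists passed at the preset correlation and none with an estimated one (adjusted p = 0.537, 0.0692, 0.227, 0.1, 0.0991 and 0.0991). The 5 erythrocyte genes were each higher adjusted over the list alone. Oligodendrocyte markers (0.19) and their precursors (0.13) passed likewise (adjusted p = 0.447 and 0.206 with an estimated correlation). Ependymal (0.26), dentate granule cell (0.10), pyramidal cell (0.02), thalamic (0.07) and cortical markers (-0.14) did not pass. With these groups moved ribosomal protein (0.19), mitochondrially encoded (0.27), nuclear respiratory chain (0.09), unfolded protein response (0.18), amyloid processing (0.09) and lipoprotein genes (0.10), again at the preset correlation alone (adjusted p = 0.228, 0.447, 0.565, 0.153, 0.15 and 0.0991 with an estimated one). The amyloid processing list includes Ide. With the noncoding level as a covariate the calls of choroid plexus (0.48, camera adjusted p = 0.114), mitochondrially encoded (0.14, camera adjusted p = 0.104), nuclear respiratory chain (0.06, camera adjusted p = 0.334) and amyloid processing genes (0.03, camera adjusted p = 0.266) ended, and medians were 0.09 for the unfolded protein response and 0.10 for endothelium, both still called. Cholesterol synthesis (0.04), heat shock (0.04), glucocorticoid (0.08) and circadian genes (-0.09) did not pass. In all, 25 of 40 lists were called higher and 2 lower, 8 of them with an estimated correlation and 12 by exact permutation of animals, namely those 8 and the endothelial, erythrocyte, unfolded protein response and amyloid processing lists. Other splits of the animals called a median of 11 lists at the preset correlation, so calls at it alone are weak.

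**Figure D4:**
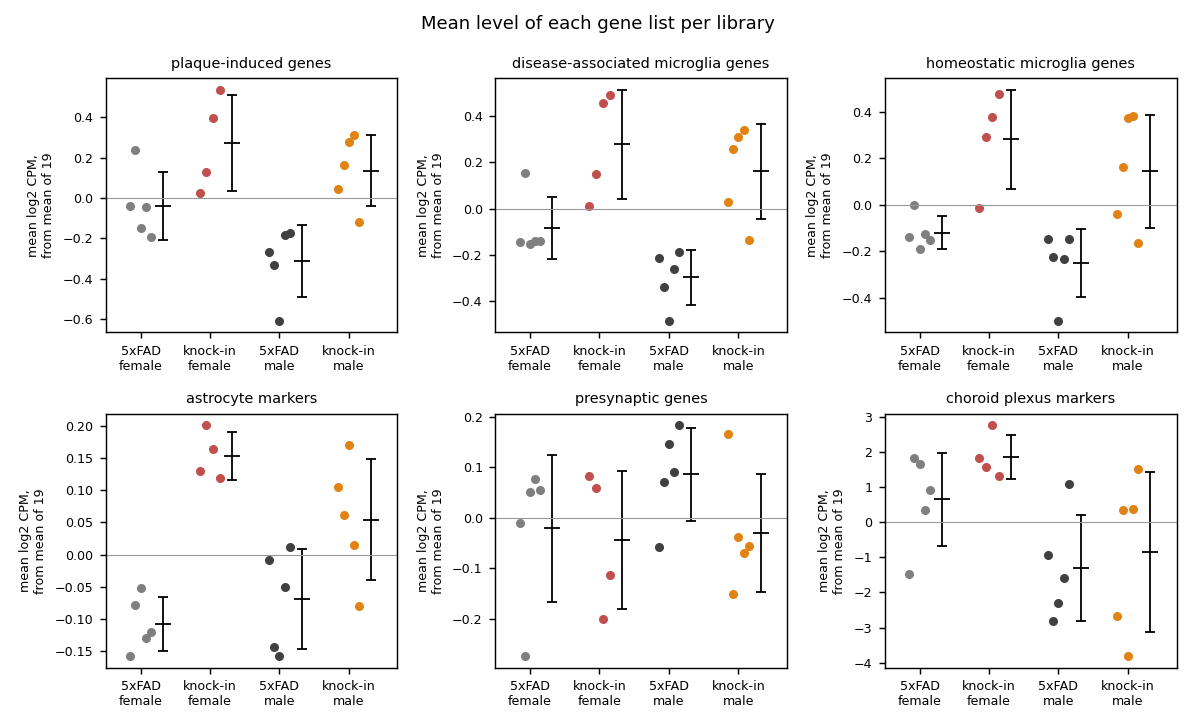
Mean log2 CPM of 6 gene lists in each animal relative to the mean of all 19, by genotype and sex (points are animals, bars the mean and SD). For plaque-induced and disease-associated genes, 5 of 5 knock-in males lie above the mean of 5xFAD males and 4 of 4 knock-in females above that of 5xFAD females, and choroid plexus markers range widely within each group.

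Within females, the knock-in came with less long noncoding RNA. Meg3, a nuclear noncoding RNA of an imprinted locus, fell from 2650 ± 325 CPM (SD, n = 5) to 562 ± 243 CPM (SD, n = 4), a log2 change of -2.24 (SE 0.43, adjusted p = 0.0121). Miat (-2.18, adjusted p = 0.0136) and Snhg11 (-2.13, adjusted p = 0.0142), also noncoding, fell alike, as did the fibrillar collagen gene Col5a1 (-2.21, adjusted p = 0.0122) and Fam227a (-2.22, adjusted p = 0.0289). Among genes that rose were Ide (1.07, adjusted p = 0.00984), the beta-globin Hbb-bt (1.09, adjusted p = 0.023), the glycogen-targeting phosphatase subunit Ppp1r3b (1.10, adjusted p = 0.0332), the gap junction gene Gjb2 (1.05, adjusted p = 0.042) and Lrch4 (1.05, adjusted p = 0.0439). In total 206 genes rose and 807 fell (43 and 1236 with library size as the only scaling), and of the latter 526 were protein-coding, 253 were not and 28 had no biotype. Among genes with a biotype, 32.5% of those that fell were not protein-coding, against 14.2% of other tested genes (Fisher's exact test, odds ratio 2.92, p = 3.24e-36, across genes, which are not independent). The 807 genes that fell also include the Y-linked, protein-coding Kdm5d (-1.52), at a level near background in females.

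Some glial genes also passed singly in females: Gfap (0.59, adjusted p = 0.0265), Cd68 (0.70, adjusted p = 0.0314), Serping1 (0.95, adjusted p = 0.037), B3gnt5 (1.46, adjusted p = 0.0303), Ctsd (0.53, adjusted p = 0.0395), Itgb5 (0.53, adjusted p = 0.0241), Serpina3n (0.60, adjusted p = 0.0402) and Olfml3 (0.52, adjusted p = 0.044), which the rule for the genotype effect had named. The 18 other members of the microglial, immune and astrocyte lists named by that rule did not pass, among them Srgn (0.61, adjusted p = 0.0524), Fcrls (0.47, adjusted p = 0.0565), Slc1a3 (0.31, adjusted p = 0.0612), Gusb (0.32, adjusted p = 0.0654), Aldh1l1 (0.39, adjusted p = 0.0658), Fcgr3 (0.36, adjusted p = 0.112), Itgam (0.34, adjusted p = 0.133), Spi1 (0.48, adjusted p = 0.135) and Cd14 (0.49, adjusted p = 0.185), up to an adjusted p of 0.819 for Cxcl10. The complement list was not called in females (median 0.29, camera adjusted p = 0.0885), with 1 member higher and 3 lower over all genes. Of the 40 lists, 19 were called higher and 0 lower, and none with an estimated correlation. Examples with members adjusted over the list alone are plaque-induced genes (median 0.35, 23 higher and 1 lower, adjusted p = 0.329 with an estimated correlation), homeostatic microglia genes (0.43, 11 higher, adjusted p = 0.303), pan-reactive astrocyte genes (0.47, 5 higher, adjusted p = 0.303) and unfolded protein response genes (0.32, 7 higher, adjusted p = 0.303). Choroid plexus (median 1.26), erythrocyte (0.97), ependymal (0.78) and mitochondrially encoded genes (0.51) were called beside them (adjusted p = 0.638, 0.303, 0.539 and 0.504 with an estimated correlation). Once the noncoding level was a covariate, 8 of these 19 lists stayed called, among them plaque-induced (0.26), disease-associated (0.25) and homeostatic microglia (0.28), pan-reactive astrocyte (0.36) and erythrocyte genes (0.81). The other 11 ended, among them choroid plexus (0.14), ependymal (0.66) and unfolded protein response genes (0.03). Antigen presentation (0.34), complement (0.26) and mural cell genes (0.23) were then called higher, and immediate early (-0.29), cholesterol synthesis (-0.17) and nuclear respiratory chain genes (-0.16) lower. Presynaptic genes did not pass (median 0.07, mean -0.02, camera adjusted p = 0.663). The count of 1013 was 0 without knock-in female 2 or 4 (3403 and 3027 genes at an unadjusted p under 0.05), 364 without 5xFAD female 1, 439 without 5xFAD female 4, and 0 with the noncoding level as a covariate, where 312 genes had an unadjusted p under 0.05. The noncoding level separates the female groups, so the 0 with it as a covariate cannot by itself tell the level from genotype. DESeq2 called 1828 genes and limma-voom 835.

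Within males, single genes did not pass, while microglial lists did. The lowest p belonged to Gusb, at 35 ± 3.75 CPM in knock-in males against 23.1 ± 1.33 CPM in 5xFAD males (SD, n = 5 each, log2 change 0.60, adjusted p = 0.0769). The microglial signalling adaptor Tyrobp (0.81), the cholesterol 25-hydroxylase Ch25h (1.39), Olfml3 (0.72) and Fcgr3 (0.64) followed, each at an adjusted p of 0.208. With edgeR 0 genes passed, while 1187 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 15 higher and 4 lower. Leaving out 5xFAD female 1 gave 2 genes and leaving out 5xFAD female 2 gave 1. Plaque-induced genes had a median log2 change of 0.43, with 37 of 53 higher adjusted over the list alone (adjusted p = 0.093 with an estimated correlation). Disease-associated microglia genes had a median of 0.48, with 14 of 34 (adjusted p = 0.093), and complement genes 0.39, with 8 of 22 (adjusted p = 0.093). Antigen presentation (0.54, adjusted p = 0.198) and type I interferon genes (0.41, adjusted p = 0.316) were called higher with 0 members adjusted over the list alone. Presynaptic (-0.13, adjusted p = 0.286), inhibitory synapse (-0.13, adjusted p = 0.286) and immediate early genes (-0.23, adjusted p = 0.477) were called lower at the preset correlation. In all 16 lists were called higher and 3 lower, and 0 with an estimated correlation.

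Whether the change with the knock-in differed between females and males is read from the interaction. The change differed between the sexes for 56 genes, of which 53 had the lower value in females. Snhg20, a noncoding host gene of a small nucleolar RNA, had a log2 change of -1.30 in females and 0.67 in males (interaction -1.98, SE 0.35), and the channel-like Tmc4 of -1.78 and 0.54 (interaction -2.32, SE 0.47). The centrosomal Lrrc45 (interaction -1.84), the ubiquitin ligase gene Rnf207 (-1.97) and the metalloprotease gene Adamts16 (-1.73) had the same sign. Ogfrl1 (0.78), the synaptic scaffold gene Lin7c (0.69) and the inhibitory G protein subunit Gnai1 (0.65) had the opposite one. All 8 had an adjusted p of 0.0499. Just short of the threshold were Col19a1 (-2.16), Dpysl4 (-0.90) and Ybx2 (-2.05) at 0.0506, and Tnip2 (-1.23) and Zgpat (-1.43) at 0.052.

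Ependymal markers had an interaction median of 1.14, erythrocyte genes 0.64, mitochondrially encoded genes 0.42, glucocorticoid genes 0.40, endothelial markers 0.21, heat shock genes 0.19, presynaptic genes 0.18, unfolded protein response genes 0.17 and interferon genes -0.39, all called at the preset correlation. With an estimated correlation the adjusted p was at least 0.878 for each of these 9. Under the noncoding covariate 1 of the 9, interferon genes (-0.37), stayed called, and plaque-induced (-0.17), cholesterol synthesis (-0.19), nuclear respiratory chain (-0.29) and ribosomal protein genes (-0.20) were called lower. The count of 56 genes was 775 with DESeq2, 0 with limma-voom (3321 genes at an unadjusted p under 0.05) and 0 with edgeR on DESeq2's size factors (3334 genes). With the noncoding level as a covariate it was 0 (622 genes at an unadjusted p under 0.05, against 3225 in the main fit). The level separates the female groups, which enter this contrast, so that 0 cannot by itself tell the level from genotype. The count was also 0 without a low-count filter (3644 of 20655 genes), with all libraries thinned to the lowest depth (3361) and with 5xFAD males 6 and 10 left out together (3121). It was 489 without knock-in male 7, 266 without knock-in female 5, 190 without 5xFAD male 6, 138 without 5xFAD male 7, 120 without knock-in male 8 and 0 without any of the other 14 libraries.

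Sex differences in 5xFAD animals were those of the sex chromosomes with 1 addition. Xist, which silences the inactive X, was at 690 ± 143 CPM in females (SD, n = 5). Over both genotypes it stood at 542 ± 205 CPM in females (SD, n = 9) and had 44 counts in total in 10 males, a ratio of 2400 over pooled counts. Eif2s3y had 0 counts in 9 of 9 female libraries and 36.3 ± 10.9 CPM in males (SD, n = 10), at least 2160-fold higher than 3 counts over the females would give. Ddx3y, with 4 counts over the females, stood at 63.8 ± 9.35 CPM in 5xFAD males (SD, n = 5). The histone demethylases Kdm5d (24 against 0.771 CPM, log2 change -4.95, adjusted p = 1.2e-09) and Uty (17.1 against 0.472 CPM, -5.18, adjusted p = 1.82e-10) have X-linked relatives that may share reads. Cpxm2, an autosomal carboxypeptidase-like gene, was at 4.4 ± 0.949 CPM in females and 1.9 ± 0.371 CPM in males (log2 change 1.21, SE 0.22, adjusted p = 0.0376). Of 7 genes called, 2 higher and 5 lower in females, 1 was X-linked and 5 Y-linked. DESeq2 called 42 genes and 1 of these 7, Xist, because its filter on mean counts kept 3836 genes and gave the other 6 no adjusted p, though all 6 kept their sign. The call of Cpxm2 ended without knock-in female 1 or 5, knock-in male 8 or 9, any of 5xFAD females 1 to 4 or any of 5xFAD males 6 to 9, with an adjusted p of up to 0.712 over its alternatives.

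Luzp2 (-0.55, adjusted p = 0.138), Gnai1 (-0.47, adjusted p = 0.146), Ogfrl1 (-0.46, adjusted p = 0.267), Kbtbd8 (-0.83, adjusted p = 0.316) and Slitrk4 (-0.48, adjusted p = 0.316) did not pass between the sexes in 5xFAD. Lists called higher in 5xFAD females were choroid plexus markers (median 1.92), antigen presentation (0.59), type I interferon (0.46, 8 of 33 adjusted over the list alone), complement (0.37), plaque-induced (0.23) and disease-associated microglia genes (0.23). Presynaptic (-0.16), heat shock (-0.14) and cholesterol synthesis genes (-0.11) were called lower. The adjusted p of each of these 9 was 0.766 with an estimated correlation. The calls of heat shock (-0.05) and cholesterol synthesis genes (-0.05) ended with the noncoding level as a covariate.

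In knock-in animals the same Y-linked genes and Xist separated the sexes, with 2 more genes higher in females. Xist was at 357 ± 55.9 CPM in females (SD, n = 4). Ddx3y was at 56 ± 6.77, Eif2s3y at 35.4 ± 3.64, Kdm5d at 23.9 ± 6.56 and Uty at 14.9 ± 1.62 CPM in males (SD, n = 5). Eif2s3x, a translation factor gene that escapes X inactivation, was at 209 ± 15 CPM in females and 118 ± 14 CPM in males (log2 change 0.82, SE 0.09, adjusted p = 2.31e-05). Cpxm2 was at 6.99 ± 1.82 and 2.08 ± 0.371 CPM (1.75, SE 0.22, adjusted p = 0.000263), a call that ended with the noncoding level as a covariate (1.70, adjusted p = 0.068) and with the authors' factors (1.18, adjusted p = 0.105). Of 9 genes called, 3 higher and 6 lower in females, 2 were X-linked, 5 were Y-linked, and besides Cpxm2 there was 1 without a placed gene model. Cdc7 (-1.02, adjusted p = 0.0576), Mrgbp (-0.76, adjusted p = 0.0616), Abcc5 (-0.88), Ddx3x (0.44) and Vmn2r115 (-0.99), the last 3 at 0.0744, did not pass.

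Choroid plexus markers were 2.75 higher at the median on the log2 scale in knock-in females than in knock-in males, and ependymal markers 1.13 higher. Their adjusted p was 0.612 with an estimated correlation, at least which all 14 called lists had. The other 12 were higher as well: pan-reactive astrocyte (0.30), leptomeningeal (0.30), erythrocyte (0.35), mitochondrially encoded (0.27), unfolded protein response (0.23), glucocorticoid (0.16), plaque-induced (0.16), homeostatic (0.15) and disease-associated microglia genes (0.13), endothelial markers (0.14), amyloid processing genes (0.10) and astrocyte markers (0.09). Given the noncoding covariate, the choroid plexus (1.84) and ependymal lists (0.90) stayed called and these 12 did not. The noncoding level was lower in these females than in knock-in males, at 6.56 against 7.80. DESeq2 called 524 genes, and the count of 9 became 340 without knock-in male 7, 324 without 5xFAD male 10, 44 without knock-in female 5 and 14 without 5xFAD male 6.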

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

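The tests of neighbouring genes, GC content, gene length, depth and the noncoding covariate were chosen after the results they bear on were seen. Tests of the noncoding level in other libraries, of the neuronal and microglial shares and of other splits of the animals were written before then. The test in other libraries used the same noncoding RNAs as the covariate, so it is not independent of that later choice.

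In knock-in females 1013 genes changed, and 0 of them passed once the noncoding RNA level was a covariate. The genes that fell then had a median log2 change of -0.15 in place of -0.99 and those that rose 0.29 in place of 0.47. The level separates the female groups, so as a covariate it overlaps with genotype there and can end calls whatever their cause. It took up most of the change of genes that fell, while genes that rose kept more of theirs. Why the calls of those that rose ended was not tested. Among the other 15 libraries, with group means removed, 97.1% of the 1006 called genes outside the noncoding set moved with the level in the direction of their call, against 68.1% of other genes, and the level predicted a median of 74.6% of the change. Of these libraries 5xFAD male 10, at 6.45 against a group mean of 7.67, lay farthest from its group and weighs most in these values. They were not recomputed without it. The level is the mean of the same RNAs as the covariate, which was chosen after seeing the data. Among these RNAs are Meg3, Miat and Snhg11, which were called lower in knock-in females. The values from the other libraries are therefore not independent of the results in females. GC content and gene length (984 calls stayed with offsets) and depth (919 stayed with all libraries thinned) do not account for the pattern. A difference in how much nuclear RNA these libraries hold may therefore account for most of the falls and part of the rises, and an effect of the knock-in on these RNAs in females stays open and untested.

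The rise of Ide was not shared by its neighbourhood, where the 20 nearest tested genes, Fgfbp3 left out, had a median log2 change of 0.017 (-0.73 to 0.45), nor did it follow the noncoding level, with which as a covariate Ide kept a log2 change of 0.72 (adjusted p = 0.0389). One more gene nearby did move: Fgfbp3, a growth factor binding protein gene, was at 10.6 ± 2.67 CPM in knock-in (SD, n = 9) and 6.49 ± 1.3 CPM in 5xFAD animals (SD, n = 10), a log2 change of 0.70 (adjusted p = 0.104, exact permutation p = 0.000504). The 3 genes between Fgfbp3 and Ide had a median of 0.05. Mouse stocks of the C57BL/6J background are known to differ in copy number at Ide and Fgfbp3, so a copy number difference between the parents of the 2 genotypes is a candidate explanation, which the value of Fgfbp3 fits. Both an effect of the knock-in on Ide and such a difference stay open, because genotype and parentage are confounded and DNA was not analysed here.

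The rise of plaque-induced and microglial lists was not taken up by the noncoding level, with which the plaque-induced list kept a median log2 change of 0.40. A lower share of neuronal RNA would raise all other cell types alike, but homeostatic microglia genes rose by 0.21 more than astrocyte, oligodendrocyte and endothelial markers (exact permutation p = 0.00976). Genes of the disease-associated list outside the homeostatic one rose by 0.41 on average and homeostatic genes outside the disease-associated one by 0.39, a difference of 0.017 (exact permutation p = 0.642). A larger share of microglial RNA in the knock-in hippocampus could give this. Bulk RNA does not show which cells the members of either list came from. Similar mean changes therefore cannot decide between such a share and a change of microglial state, and both stay open. So does a difference of colony, cohort or library batch, with which genotype is confounded.

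Other splits of the animals, 100 for each comparison with the real one included, bear on chance. For the genotype effect, 1 split, the real one, gave as many genes (4 real, 1 at most in the others). As many lists came from 2 splits (27 real, 28 in the highest other). With an estimated correlation 1 split gave as many lists (8 real, 5 in the highest other). Such counts were rare by chance, but 100 splits and several counts do not exclude it. At the preset correlation the other splits of each comparison called a median of 9 to 11 lists. For females no other split came near the count of genes (1 split, 1013 real, 1 in the highest other). The noncoding level separates the female groups, so every other split mixes its levels. The count therefore cannot tell the knock-in from that level or from another state of the libraries. For lists chance cannot be excluded (15 splits, 19 real, 25 in the highest other). For males the real count of genes is 0, which 100 of 100 splits reach by construction, so that count tests nothing, and chance cannot be excluded for lists (10 splits, 19 real, 24). Another split of the males gave 788 genes, which points to a structure of the samples whose nature was not tested. For the interaction only the real split gave as many genes (56 real, 0 in the others), with the same limit as for females. Chance cannot be excluded for lists there (68 splits, 9 real, 23). For the sex effect in 5xFAD, 1 split gave as many genes (7 real, 1 in the highest other). Of these 7, 1 is X-linked and 5 are Y-linked, and a split that mixes the sexes cannot reach them. The count therefore does not bear on chance for Cpxm2, the other call. For lists chance cannot be excluded there (53 splits, 9 real, 21). In knock-in animals chance cannot be excluded from the number of genes (5 splits, 9 real, 605 in the highest other) or lists (29 splits, 14 real, 20). Of the 9 genes 7 are X- or Y-linked and follow the sex itself, such as Ddx3y, at 0 CPM in knock-in females and 56 ± 6.77 CPM in knock-in males (SD, n = 5, adjusted p = 3.32e-13), and Cpxm2 separated the sexes without overlap in knock-in animals (5.04 to 9.41 CPM in females and 1.76 to 2.6 CPM in males) and in 5xFAD animals (3.07 to 5.62 and 1.55 to 2.51 CPM), although its call depends on the model (adjusted p up to 0.105 in knock-in animals). Genes short of the threshold also separated the sexes without overlap, such as Cdc7 in knock-in animals and Luzp2 in 5xFAD animals. In 5xFAD animals the adjusted p of Cpxm2 reached 0.712 over its alternatives. Chance is therefore not excluded for Cpxm2, and it stays open for the 1 gene left. The split with 605 genes again points to a structure of the samples that was not examined.

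The genotype effect differed between females and males, by the interaction test, for 56 genes, all at an adjusted p of 0.0499. The count was 0 with the noncoding level as a covariate (622 genes at an unadjusted p under 0.05), where Tmc4 had an interaction of -0.67 and Snhg20 of -1.31, and 0 with thinning, without a filter and with 5xFAD males 6 and 10 left out. Those named were Tmc4 (-2.32), Snhg20 (-1.98), Rnf207 (-1.97), Lrrc45 (-1.84), Adamts16 (-1.73), Ogfrl1 (0.78), Lin7c (0.69) and Gnai1 (0.65). Over all alternatives each of them kept its sign. Their weakest values were -0.67, -1.31, -0.89, -0.72, -1.14, 0.65, 0.35 and 0.52, in the same order. By the same contrast, at the preset correlation, lists differed with medians of 1.14 (ependymal), 0.64 (erythrocyte), 0.42 (mitochondrially encoded), 0.40 (glucocorticoid), 0.21 (endothelial), 0.19 (heat shock), 0.18 (presynaptic), 0.17 (unfolded protein response) and -0.39 (type I interferon), and with an estimated correlation 0 of these 9 passed (adjusted p at least 0.878).

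Single animals lay far from the rest of their group in 28 of 440 groups of values (6.36%), where chance gives 22 at 1 in 20. Knock-in female 5 had 25.2 M counts (M stands for mega). Among genes, in CPM, Col5a1 was at 37.6 in knock-in male 10, Gfap at 1110 in 5xFAD female 2, Homer1 at 141 in knock-in female 2 and 224 in 5xFAD female 4, Psmb8 at 14.6 and Rnf207 at 3.07 in knock-in female 5, and Hspb1 at 21.2 and Serping1 at 14 in knock-in male 7. Cd68 was at 22 in 5xFAD male 7, Col19a1 at 18.3 in 5xFAD female 4, Gjb2 at 9.23 in 5xFAD male 8, Itgam at 50.9 in knock-in female 2, Itgax at 18 in knock-in male 9, Lin7c at 158 in 5xFAD male 6, Mlc1 at 236 in knock-in female 1 and Npas4 at 44.3 in 5xFAD female 1, each the highest of its group. The lowest of their group were Fam227a at 2.52 and Tgm1 at 0.0547 in 5xFAD female 1. Among list means, in log2 CPM from the mean of all animals, the highest were 0.15 for disease-associated microglia genes and 0.083 for oligodendrocyte precursors in 5xFAD female 2, 0.072 for pan-reactive astrocyte genes in 5xFAD male 6 and 0.42 for the A2-type list in knock-in male 7. The lowest were -0.50 for homeostatic microglia and -0.76 for interferon genes in 5xFAD male 8, -0.27 for presynaptic genes in 5xFAD female 2, 0.070 for amyloid processing genes in knock-in female 1 and -0.24 for nuclear respiratory chain genes in knock-in female 2.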

How the results depend on the processing

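The noncoding covariate, GC and length offsets, thinning, the authors' factors, leaving out 5xFAD males 6 and 10 together, and the permutation and deposited-value versions of the list tests were chosen after seeing the data, and all other alternatives before the data were examined. At these depths and numbers of animals small changes were mostly missed: of genes simulated at the smallest fold, 20% were recovered for the genotype effect and 4% for the interaction. Thinning to the lowest depth left 4 genes for the genotype effect.

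The level of Clu kept its sign and stayed short of the threshold in 33 of 33 alternatives (log2 change 0.02 to 0.19, adjusted p 0.347 to 0.999). For single genes and lists, 4217 values were computed under alternatives, of which 3397 kept direction and side of the threshold, 683 lost the threshold, 128 gained it and 9 reversed. The cause was not tested for any count unless a reason stands beside it.

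Counts of genes moved as follows where they moved by more than 1.5 times. For the genotype effect (4), DESeq2 gave 108, limma-voom 2, library size only 1, no sex term 2, the authors' factors 1, the noncoding covariate 2 (1 among the 4), GC and length offsets 2, both males left out 14, and single libraries left out 1 to 127. For females (1013), DESeq2 gave 1828, female libraries alone 1603, the noncoding covariate 0, GC and length offsets 1541 (516 higher, 1025 lower), and single libraries left out 0 (without knock-in female 2 or 4) to 1334 (without 5xFAD male 10). For males (0), DESeq2 gave 19, library size only 1, and single libraries left out 0 to 2 (without 5xFAD female 1). For the interaction (56), DESeq2 gave 775, library size only 402 (with a median log2 change of all genes of -0.15), GC and length offsets 169, and limma-voom, DESeq2's size factors, no filter, 1 surrogate variable, the authors' factors, the noncoding covariate, thinning and both males left out each 0. Single libraries left out gave 0 to 489 (without knock-in male 7). The adjusted p of all 56 genes lies just under the threshold at 0.0499, so even small shifts can end or multiply the calls. The shift was not small with the noncoding covariate, where genes at an unadjusted p under 0.05 went from 3225 to 622. For the sex effect in 5xFAD (7), DESeq2 gave 42, 1 of them among the 7, as its filter on mean counts gave the other 6 no adjusted p, and single libraries left out 6 to 7. In knock-in animals (9), DESeq2 gave 524, the authors' factors 14, GC and length offsets 24, both males left out 342, and single libraries left out 8 to 340 (without knock-in male 7).

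Counts of lists moved mainly with the test. For the genotype effect (27), an estimated correlation left 8, directional fry 16, mixed fry 8 and exact permutation of animals 12, and single libraries left out gave 24 to 28. For females (19) an estimated correlation and permutation left 0 and directional fry 10. Mixed fry gave 13, 9 of them among the 19, and the noncoding covariate 14 (11 higher, 3 lower), 8 of them among the 19. For males (19) these gave 0, 0 and 5, and mixed fry 4. For the interaction (9), an estimated correlation and directional fry left 0. Mixed fry called 1 list, not among the 9, and the noncoding covariate 5, all lower and 1 of them among the 9. For the sex effect in 5xFAD (9) and in knock-in animals (14), an estimated correlation, both fry tests and permutation left 0. Both males left out gave 14 lists in 5xFAD, and the noncoding covariate gave 7 in knock-in animals, 2 of them among the 14. An estimated correlation takes up shared variation of the genes of a list, which the preset correlation of 0.01 sets low. Within 1 sex or genotype the smallest exact permutation p is 0.0079, so after adjustment over 40 lists a call needs several lists at that floor, and counts of 0 by permutation there show little.

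With the noncoding covariate 9 values changed sign, none of them past the threshold: Fam227a (0.35), amyloid processing (-0.029), ribosomal protein (-0.0073) and heat shock genes (-0.17) in females, heat shock (-0.079) and unfolded protein response genes (-0.020) in the interaction, and astrocyte (-0.0043), leptomeningeal (-0.029) and amyloid processing genes (-0.0175) in the sex effect of knock-in animals.

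The replicate numbers in the labels recur in both genotypes, but same-numbered animals did not deviate together: correlations ran from -0.203 to 0.119 over 9 pairs, 2 of them over 0.1, and 1 of the 5xFAD libraries correlated best with its own number. With the replicate number as a block the genotype effect gave 0 genes by edgeR (1291 at an unadjusted p under 0.05), the females 678, the males 0, and the lists 26.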

Other observations

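The comparisons of signs between the sexes and of ranges between animals were chosen after the values were seen, as was Ttr.

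Log2 changes with genotype in females and males were uncorrelated gene by gene, but the glial lists had the same sign in both. Across 14215 genes with a mean of at least 1 log2 CPM, the log2 changes of females and males had a Pearson r of -0.0089, across genes, which are not independent. Of the 1013 genes called in females, 423 (41.8%) had the same sign in males, namely 124 of the 206 that rose and 299 of the 807 that fell. Both contrasts rest on 4 or 5 animals per group. The noncoding level also differed by genotype in females (6.56 in knock-in against 8.21 in 5xFAD) and hardly in males (7.80 against 7.67). Neither r nor this share therefore measures how much of the genotype effect the sexes share. Of 53 plaque-induced genes, 52 had a log2 change above 0 in females and 53 in males. The counts were 34 and 29 of 34 for disease-associated microglia genes, 18 and 18 of 18 for homeostatic microglia genes, and 15 and 14 of 16 for astrocyte markers. The interaction of these 4 lists did not pass (camera adjusted p = 0.554, 0.872, 0.797 and 0.083), which does not show that the sexes responded alike. With the noncoding level as a covariate the plaque-induced list was called lower in the interaction (-0.17, camera adjusted p = 0.00379). Ide, the protease of insulin and amyloid-beta, was at 109 ± 14.8 CPM in knock-in and 51.7 ± 14.7 CPM in 5xFAD females (SD, n = 4 and 5), and at 90.8 ± 10.6 and 57 ± 8.25 CPM in males (SD, n = 5 each, adjusted p = 0.433 within males).

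Markers of tissue next to the hippocampus varied widely between animals. The mean of choroid plexus markers, genes of the epithelium that makes cerebrospinal fluid, ranged from -3.82 in knock-in male 8 to 2.76 in knock-in female 4, in log2 CPM from the mean of all animals. Within knock-in females it ran from 1.32 to 2.76, within knock-in males from -3.82 to 1.52, within 5xFAD females from -1.46 to 1.83 and within 5xFAD males from -2.82 to 1.09. Ttr, the thyroid hormone carrier made there, averaged 5203 CPM in knock-in females, 1499 CPM in knock-in males, 3003 CPM in 5xFAD females and 1032 CPM in 5xFAD males. Ependymal markers ranged from -1.72 in 5xFAD female 1 to 1.66 in knock-in female 1, and leptomeningeal markers from -0.91 in knock-in male 6 to 1.13 in knock-in male 7.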
